A study of Zea mays with 27 samples.

How the data were processed

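Leaf RNA of adult maize plants was measured on 27 dual-colour cDNA arrays. Each array carried RNA of 1 group in 1 dye and RNA of another group, most often b,pl plants under the CA filter, in the other dye. Groups and dyes were taken from the array titles. On 4 arrays the channel 2 source name ends in Cy3 although the title gives Cy5, and the titles were followed there. These arrays with conflicting dye labels are b,pl PE removed replicate 2, B,Pl PE replicate 2 and the only arrays of bz2 CA and mutator CA.

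The deposited values are log2 ratios of the channels of each array, 1 value per spot. The base was read from the values: of the values over 2 in size, 14.9% had a base 2 antilog that was whole within 0.0001, against 0.095% for base e. The authors' scanner settings, background correction, normalisation and the channel used as numerator are not given in the sources used here, and channel intensities were not analysed here. Deposited values were present for 14715 to 16122 of the 16200 spots per array. Array medians lay between −0.691 and 0.367, so the deposited values were not centred on 0. The number of arrays limits the precision.

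Spots came in consecutive triplicates with the same annotation. The median SD within such triplicates was 0.038, against 0.185 for triplicates shifted by 1 spot. The layout was read from the values and the annotation, and the 3 spots were averaged, which gave 5400 cDNAs, and each array was centred on its median. A cDNA had to have a value on at least 14 arrays, and all 5400 did. A probe annotation table gave 1 gene symbol for 811 cDNAs and none for the other 4589, and 0 spots carried several symbols. The named cDNAs stood for 213 genes, of which 208 were matched to the gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. The annotation is old, and cDNAs cross-hybridise between close family members such as tubulins, elongation factors, HSP70 and glyceraldehyde-3-phosphate dehydrogenases. No genome coordinates were used.

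All arrays entered 1 linear model with 19 terms, which were 18 groups relative to b,pl under CA and a dye term. A group counted as positive when labelled Cy5 and as negative when labelled Cy3. This left 8 residual degrees of freedom, to which the variance shrinkage of limma 3.58.1 in R 4.3.3 added 2.42. The model was solved by least squares for each cDNA over the arrays that measured it, since lmFit's contrasts are approximate where arrays are missing, and the variances were then shrunk with squeezeVar as in eBayes. On the 4651 cDNAs with a value on every array, 0 differed from lmFit and eBayes in any t by more than 1e-10. The adjusted p is that of Benjamini and Hochberg over the cDNAs, with both directions tested and a threshold of 0.05, and 19 comparisons and 2 F tests of genotype differences were specified before the data were examined. The b,pl CA RNA served as the control on the other channel, so its own spread is left out. Comparisons that share a group are not independent of each other. A group with 1 array was assumed to vary like the others. The labels do not say whether arrays of a group, including dye swaps, came from separate plants, so the p-values measure the spread between these arrays, which may be technical only.

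The fit was tested on simulated data with 100 cDNAs changed by 1 and 100 by 2 on the log2 scale. The fewest changed by 1 were recovered for bz2 against b,pl at greenhouse UV-B, 1 of 100 among 5393 cDNAs. The fewest changed by 2 were recovered for B,Pl against b,pl at greenhouse UV-B, 31 of 100 among 5379. The most were recovered for B,Pl against b,pl under CA, 45 and 85 of 100 among 5400. Unchanged cDNAs made up 4.87% of the calls over the 19 simulations and from 0% to 11.3% in single ones, with 8 of 71 calls for B,Pl under LE among 5370 cDNAs and 14 of 129 for b,pl at greenhouse UV-B against CA among 5399. Without any change, 4.56% to 5.48% of the unadjusted p-values lay under 0.05. The simulated noise was normal and independent between cDNAs and arrays, with the fitted spread of each cDNA and all dye labels taken as right. Rates near 5% follow from that setting. They check the code and do not show that p-values are calibrated on the real arrays, where cDNAs correlate and some dye labels are in doubt.

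The rule for named cDNAs was specified beforehand: up to 10 positive and 10 negative among those past the threshold with the same sign on every array that sets the groups side by side, up to 4 passing members of each gene list, and, where fewer than 5 cDNAs passed, the 5 named cDNAs with the smallest p. Values given for genes named by this rule are those of single cDNAs, and other cDNAs of the same gene can differ in sign. Of 12 flavonoid genes to be named wherever measured (b1, pl1, r1, c1, c2, whp1, a1, a2, bz1, bz2, pr1 and chi1), 0 were among the annotated cDNAs. Gene lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over 437 tests, and again with the estimated correlation. Of 21 lists written beforehand, 13 held no annotated cDNA and 5 had the 3 cDNAs needed for a test. A further 18 lists were written after the annotation and the correlations between arrays had been seen and before any test of genes or lists, and all 18 were tested, so that 23 lists met 19 comparisons.

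The alternatives tried were no centring, no dye term, scaling of arrays to 1 spread, complete cDNAs, no filter, robust shrinkage, a 2-fold rule and leaving out each array in turn. After the data had been seen, further alternatives were added: values read as group over other channel, the sign of 1 array turned, leaving out the 3 arrays with the most missing values, averaging the cDNAs of a gene, list medians with each array left out, with 1 sign turned and read as group over other channel, and comparisons averaged over genotypes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.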

Results

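Leaf transcripts were compared among maize genotypes of differing flavonoid background under filters and UV-B treatments. B and Pl regulate anthocyanin synthesis, and Bz2 encodes a glutathione S-transferase needed to move anthocyanin into the vacuole. The genotypes were b,pl, B,Pl, bz2 and a line labelled mutator. Plants stood under plastic filters labelled CA, PE or LE, were sampled 1 day after the PE filter was removed, or stood in a greenhouse with 8 h of supplementary UV-B or without UV-B. For b,pl there were 2 arrays each for LE, PE, PE removed and greenhouse UV-B, and 1 for greenhouse without UV-B. For B,Pl there were 3 arrays for PE, 2 each for CA and PE removed, and 1 each for LE and UV-B. For bz2 there were 2 arrays for LE and 1 each for CA, PE and UV-B, and mutator had 1 array for each of these 4. Each array measured 14715 to 16122 spots, averaged to 5400 cDNAs, of which 811 carried names of 213 genes.

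The labels give the dyes but not which channel is the numerator. A positive value means that the first-named group had more RNA if the deposited values are Cy5 over Cy3, and less if they are Cy3 over Cy5. The values were read by dye because the median residual variance was 0.168 that way and 0.216 when read as group over other channel, and it was smaller by dye for 61.9% of cDNAs. The same-dye arrays b,pl PE removed replicate 1 and b,pl greenhouse UV-B replicate 2 correlated at Pearson −0.40 over cDNAs, which leaves their direction relative to each other unsettled. Turning the sign of the greenhouse array raised the median residual variance from 0.168 to 0.205, and as labelled it lay at a Spearman correlation of −0.40 with its dye swap. For b,pl PE removed replicate 1 these values were 0.161 and 0.14, so its direction stays open. Its dye swap, b,pl PE removed replicate 2, has conflicting dye labels, and with that array turned the variance was 0.167. Between the arrays of a dye swap a group difference has opposite signs. Of 8 such pairs, 4 had a Spearman correlation below 0 over cDNAs, which are not independent replicates, from −0.55 for bz2 LE to −0.22 for b,pl LE and B,Pl PE removed, and the other 4 ran from 0.04 for B,Pl CA to 0.61 for B,Pl PE. Without centring, the median of all cDNAs moved to between −0.44, for bz2 minus b,pl under CA, and 0.48, for b,pl under LE. Leaving out the centring moves the cDNAs of a comparison together, and by that common shift 8 of the 81 list medians called below changed sign; relative to the shifted median 0 did, which follows from the common shift, and 0 did with scaled arrays, where 8 moved by over 1.5 times. Read as group over other channel, a step added after the data were seen, 20 of the 81 changed sign and 25 others moved by over 1.5 times. When the values of 1 array were turned, 5 changed sign for b,pl PE replicate 2, 3 for b,pl UV-B replicate 2, 2 for b,pl PE removed replicate 1 and 1 for B,Pl PE replicate 3. With 1 array left out, a step added after the data were seen, 6 of the 81 changed sign and 26 others moved by over 1.5 times.

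In bz2 under LE against CA, 30 cDNAs passed, 10 positive and 20 negative, and 5 of them were named. One cDNA of hsp70-4, an HSP70 chaperone gene, stood at 1.56 (SE 0.20, limma adjusted p = 0.00932), although 18 of the 21 cDNAs of this gene were negative. The glycolytic enzyme gene eno1 (LOC732811, enolase) had a cDNA at 0.93 (SE 0.17, limma adjusted p = 0.0467), with 5 of its 5 cDNAs positive. The elongation factor genes elfa2 (LOC100037748) and elfa3 (LOC542620), which carry aminoacyl-tRNA to the ribosome, had cDNAs at −1.35 (SE 0.24) and −1.12 (SE 0.21), with limma adjusted p of 0.0376 and 0.0467, and 13 of 13 and 31 of 35 cDNAs negative. A cDNA of LOC542721 stood at −1.87 (SE 0.32, limma adjusted p = 0.0358), and the other cDNA of this gene was positive. Over 39 alternatives the limma adjusted p of the hsp70-4 cDNA ran from 0.00724 to 1 and passed in 35; it was 0.0846 without bz2 LE replicate 1 and 0.11 without replicate 2. The eno1, LOC542721, elfa2 and elfa3 cDNAs passed in 15, 21, 21 and 19 of the 39, and each failed without any 1 of bz2 LE replicate 1, both arrays of b,pl LE, b,pl UV-B, b,pl PE removed and B,Pl PE removed, B,Pl PE replicates 1 and 2, and B,Pl CA replicate 1. Without bz2 LE replicate 2 eno1, elfa2 and elfa3 failed too, without B,Pl PE replicate 3 eno1, LOC542721 and elfa3, and without either b,pl PE array or B,Pl CA replicate 2 eno1. When the sign of b,pl PE replicate 2 was turned, eno1 and elfa3 failed. Without bz2 LE replicate 1 their limma adjusted p was 0.29, 0.337, 0.316 and 0.262. Read as group over other channel, all but LOC542721 took the opposite sign.

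As a group, the 58 cDNAs of 3 elongation factor 1-alpha genes had a median of −0.66 in bz2 under LE. The 56 cDNAs for S-adenosylmethionine and inositol synthesis had one of 0.68, and the 63 cDNAs of linker histones H1 one of 0.18, which was −0.03 without centring, where all cDNAs had −0.21. HSP70 (43 cDNAs of 2 genes) stood at −0.20, and the lists of heat shock proteins (−0.20) and translation factors (−0.33) written beforehand were also called. The heat shock list has 49 cDNAs of 5 genes, and its medians here and below repeat or nearly repeat those of HSP70. These 2 lists appear to share most of their cDNAs, so their calls are not independent of each other. Without bz2 LE replicate 2 HSP70 and the heat shock list stood at 0.041 and 0.015, and without replicate 1 at −0.41 and −0.38. As group over other channel all 6 lists took the opposite sign: elongation factor 1-alpha stood at 0.066, the S-adenosylmethionine and inositol list at −0.11, linker histones at −0.0099, HSP70 and the heat shock list at 0.12 and translation factors at 0.018. All these calls were lost when the test used list correlations estimated from the data (adjusted p = 0.984 with an estimated correlation). At unadjusted p under 0.05, 774 cDNAs passed in this comparison. The count of 30 was 11 without any 1 of b,pl PE removed replicates 1 and 2, b,pl LE replicates 1 and 2 and B,Pl CA replicate 1, 12 without B,Pl PE replicate 2, 13 without either b,pl UV-B replicate and 17 without either B,Pl PE removed replicate. It was 6 without centring, 1 of them positive, 12 with scaled arrays, 5 of them positive, 16 without the 3 arrays with the most missing values, 7 of them positive, 14 read as group over other channel, all 14 positive, and 53 with the sign of B,Pl PE replicate 3 turned, 24 of them positive.

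In B,Pl under LE against CA, with 1 array, the list of S-adenosylmethionine and inositol synthesis had the largest median of any list in the 19 comparisons, 1.25, with 51 of 56 cDNAs positive. It holds sam2 (LOC542733), an S-adenosylmethionine synthetase, a further synthetase gene, and INO1 (LOC542540), which makes inositol phosphate. Over the list alone 19 cDNAs passed and over all cDNAs 0. The mitochondrial membrane proteins (0.25) and the glycolysis, sucrose and starch genes (0.13, and −0.04 without centring, where all cDNAs had −0.17) were positive. HSP70 (−0.09), small heat shock proteins (−0.34) and the heat shock list written beforehand (−0.10) were negative. With scaled arrays HSP70 stood at −0.14 and the heat shock list at −0.16. Read as group over other channel, the S-adenosylmethionine and inositol list stood at 0.59, the glycolysis list at 0.21, HSP70 and the heat shock list at −0.17 and small heat shock proteins at −0.19. These calls ended with estimated correlations (adjusted p = 0.984 to 0.986 with an estimated correlation). Of single cDNAs, 13 passed in limma, 7 positive and 6 negative, none of them named, and 234 at unadjusted p under 0.05, against 268 by chance. An unnamed cDNA beginning at spot 11929 stood at 4.54 (SE 0.43, adjusted p = 0.00295) and another at spot 13537 at −3.61 (SE 0.30, adjusted p = 0.000876). The count was 7 or 8 without any 1 of the b,pl and B,Pl PE removed arrays, both b,pl LE arrays, both b,pl UV-B arrays, B,Pl PE replicate 2 and B,Pl CA replicate 1, and 48 with scaled arrays, 32 of them positive.

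Mutator plants under LE against CA, with 1 array, had 53 of 56 cDNAs of the S-adenosylmethionine and inositol list positive, at a median of 1.07, which was 0.65 read as group over other channel. For sam2, 30 of 32 cDNAs were positive and for INO1 19 of 19, with single cDNAs at 1.63 (SE 0.41), 1.55 (SE 0.42) and 1.45 (SE 0.35). An eno1 cDNA stood at 0.91 (SE 0.25) and 1 of tua5 (LOC542248), an alpha-tubulin, at −1.18 (SE 0.27). None of these 5 cDNAs passed (limma adjusted p from 0.46 to 0.531). Aquaporins, the water channels, had a median of 0.34. The list calls did not hold (adjusted p = 0.984 with an estimated correlation). Of single cDNAs, 3 passed in limma, all unnamed, against 322 at unadjusted p under 0.05. They began at spots 6115, 13177 and 3049 and stood at 3.73 (SE 0.43), −3.28 (SE 0.33) and −2.40 (SE 0.26). The count was 6 without bz2 LE replicate 1 or 2.

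In b,pl under LE against CA, both cDNAs of LOC542592, a reversibly glycosylated polypeptide, were positive at 1.54 (SE 0.23) and 1.33 (SE 0.29). The methionine pathway gene cgs1 (LOC541650, cystathionine gamma-synthase) stood at 0.85 (SE 0.18). A tua5 cDNA stood at −0.87 (SE 0.18), although 5 of the 8 cDNAs of this gene were positive. A cDNA of PEAMT, a methyltransferase of choline synthesis, stood at −1.75 (SE 0.39), with 4 of 5 negative. None of them passed (limma adjusted p of 0.233 for the first and 0.55 for the others). The S-adenosylmethionine and inositol list had a median of 0.48 and mitochondrial membrane proteins 0.30, while the heat shock list written beforehand had −0.07, which was 0.41 without centring, where all cDNAs had 0.48, 0.022 without b,pl LE replicate 1, −0.19 without replicate 2 and −0.13 with scaled arrays. As group over other channel these 3 lists stood at −0.13, 0.11 and −0.17. These calls were lost on estimation (adjusted p = 0.984 with an estimated correlation). In limma 0 cDNAs passed and 354 had an unadjusted p under 0.05. Without b,pl LE replicate 1 the count was 103, and an LOC542592 cDNA and PEAMT passed, at 1.98 and −2.81.

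Averaged over the 4 genotypes, a comparison added after the data were seen, LE against CA gave 69 passing cDNAs, 49 positive and 20 negative, and 27 of them were named. They included 14 of the 32 sam2 cDNAs, from 0.71 to 1.26, and 3 of the 19 INO1 cDNAs, from 0.92 to 1.41. The count was 0 without b,pl LE replicate 2, 17 without B,Pl CA replicate 1, 23 and 27 without bz2 LE replicate 2 and 1, 39 without either b,pl UV-B array, and 41 without B,Pl PE replicate 1 or 2. It was also 0 without the 3 arrays with the most missing values, 2 without centring, both positive, 120 with scaled arrays, and 3 read as group over other channel. At unadjusted p under 0.05, 919 cDNAs passed.

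The F test of whether genotypes differed in their LE response gave 13 cDNAs in limma, all unnamed, and 217 at unadjusted p under 0.05. In 8 of the 13 the value farthest from the median of the genotypes was that of B,Pl, in 3 that of bz2, in 2 that of mutator and in 0 that of b,pl. The count was 46 without b,pl LE replicate 1 and 2 without b,pl LE replicate 2, 27 and 34 without bz2 LE replicates 1 and 2, and 4 without B,Pl PE replicate 2. It was 5 without either B,Pl PE removed or b,pl UV-B array, 6 without either b,pl PE removed array, 7 without B,Pl CA replicate 1 and 8 without B,Pl PE replicate 1 or 3. With scaled arrays it was 27 and without centring 1.

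**Figure D1:**
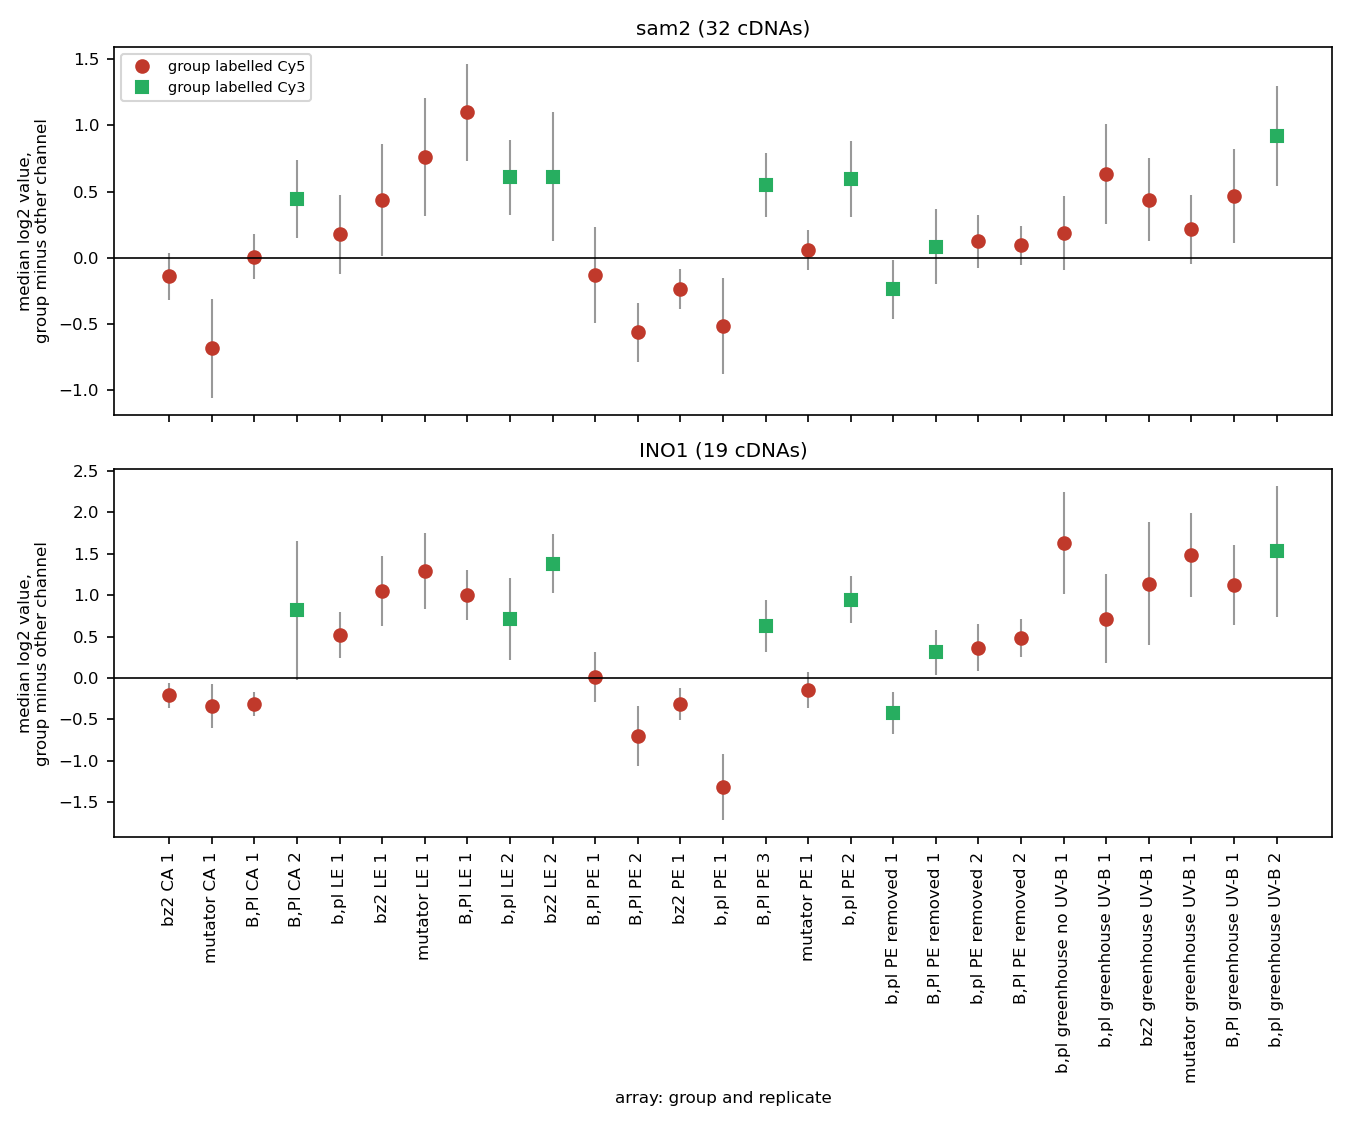
Median log2 value of the sam2 cDNAs (top) and INO1 cDNAs (bottom) on each of the 27 arrays, turned to group minus other channel as if values were Cy5 over Cy3 (vertical axis), with bars of 1 SD between cDNAs, by group and replicate (horizontal axis), and colour and shape for the dye of the group. Both genes lie above 0 on 6 of 6 LE arrays and 6 of 6 greenhouse arrays, the array without UV-B included, and read as group over other channel on 4 and 5 of the 6.

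Under PE against CA, b,pl had a sam2 cDNA at 1.32 (SE 0.30), HDT1 (LOC542355), a histone deacetylase of the HD2 type, at 1.43 (SE 0.37), calmodulin CaM1 (LOC542420) at −1.19 (SE 0.29), LOC542657 at −1.12 (SE 0.28) and fdh1 (LOC542459) at −1.63 (SE 0.43). None of these 5 passed (limma adjusted p = 0.391 for each). Elongation factor 1-alpha had 57 of 58 cDNAs negative, at a median of −0.37, but the list stood at 0.11 on b,pl PE replicate 1 and −0.82 on replicate 2, and without replicate 2 the median was 0.0046 with 27 of 58 negative. Translation initiation factors stood at −0.35, HSP70 at −0.17, and the translation factor and heat shock lists written beforehand at −0.41 and −0.17. The initiation factors and the translation factor list stood at −0.019 and −0.052 without replicate 2, and without replicate 1 both were at −0.74 and elongation factor 1-alpha at −0.72. The direction of replicate 2 is in doubt, since turning its sign took the median residual variance from 0.168 to 0.158. Turning replicate 1 instead gave 0.164, and the Spearman correlation of 0.10 between both arrays does not tell which is at fault. Values with replicate 1 turned were not computed. With the sign of replicate 2 turned, and likewise read as group over other channel, elongation factor 1-alpha stood at 0.48 with 57 of 58 cDNAs positive, initiation factors at 0.23, the translation factor list at 0.24, and HSP70 and the heat shock list at −0.049 and −0.047, while all of these 5 cDNAs but sam2 took the opposite sign. With scaled arrays elongation factor 1-alpha stood at −0.18 and the translation factor list at −0.26. Over all cDNAs 45.8% had the same sign on both arrays, against 50% by chance. The list calls were lost (adjusted p = 0.984 to 0.986 with an estimated correlation). Over all cDNAs 0 passed in limma and 574 had an unadjusted p under 0.05. Without b,pl PE replicate 1 the count was 645, and all of these 5 but sam2 passed.

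In B,Pl under PE against CA, 91 of 117 tubulin cDNAs were negative (median −0.40), as were 41 of 43 HSP70 cDNAs (median −0.39) and the heat shock list written beforehand (−0.38). Without B,Pl PE replicate 1 the tubulin median was −0.14. The direction of B,Pl PE replicate 3 is in doubt: it had a Spearman correlation of 0.61 with its dye swap, and turning its sign took the median residual variance from 0.168 to 0.152. That dye swap, B,Pl PE replicate 2, has conflicting dye labels, and turning it instead gave 0.166. With replicate 3 turned the medians of tubulins, HSP70 and the heat shock list were −0.52, −0.56 and −0.53, with 92 of 117 tubulin and 40 of 43 HSP70 cDNAs negative. Single cDNAs stood at −0.82 (SE 0.21) for tua4, an alpha-tubulin, −1.02 (SE 0.29) for HDT1, −0.88 (SE 0.25) for LOC542041, −0.81 (SE 0.23) for the lipoxygenase lox1 and 0.52 (SE 0.15) for stomatin1 (LOC541819). Of these 5 cDNAs 0 passed (limma adjusted p = 0.53 for each), and the list calls were lost (adjusted p = 0.984 with an estimated correlation). Over all cDNAs 0 passed in limma and 488 had an unadjusted p under 0.05.

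In bz2 under PE against CA, with 1 array, ribosomal proteins (−0.44), mitochondrial membrane proteins (−0.32), elongation factor 1-alpha (−0.28) and tubulins (−0.25) had negative medians. That of elongation factor 1-alpha was −0.16 with the sign of b,pl PE replicate 2 turned and 0.024 read as group over other channel. All 12 cDNAs of the adenine nucleotide translocator ANT1 (LOC542386) were negative, 1 of them at −0.70 (SE 0.30). Others stood at 0.95 (SE 0.22) for stomatin1, 0.66 (SE 0.24) for GIF1 (LOC100101544), −0.83 (SE 0.32) for pep7 (LOC542479) and 1.03 (SE 0.42) for ocl4 (LOC542009). These 5 cDNAs did not pass (limma adjusted p = 1), and the list calls were lost (adjusted p = 0.984 with an estimated correlation). Limma passed 0 cDNAs, and 95 had an unadjusted p under 0.05, against 269 by chance. The count was 1 without B,Pl CA replicate 1.

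In mutator under PE against CA, with 1 array, tubulins had a median of −0.32 and HSP70 of 0.28, which was 0.175 read as group over other channel and −0.11 without centring, where all cDNAs had −0.39, as the heat shock list written beforehand went from 0.25 to −0.13. Named cDNAs stood at −0.88 (SE 0.24) for cys2 (LOC542438), 1.47 (SE 0.41) for LOC541772 and −0.81 (SE 0.27) for SET102 (LOC542678). A further cDNA stood at 1.40 (SE 0.43) for the homeobox gene hox3 (LOC542440) and 1 at 1.23 (SE 0.42) for ocl4, although 2 of the 3 cDNAs of each gene were negative. None of these 5 passed (limma adjusted p = 1), nor did the lists (adjusted p = 0.984 with an estimated correlation). In limma 0 cDNAs passed and 159 had an unadjusted p under 0.05, against 270 by chance.

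Averaged over genotypes, a comparison added after the data were seen, PE against CA gave 0 passing cDNAs in limma and 611 at unadjusted p under 0.05. The F test of whether genotypes differed in their PE response gave 0 and 67, where chance gives 269 for 5375 cDNAs. Without b,pl PE replicate 1 the counts were 211 and 204, and without B,Pl CA replicate 1 both were 1.

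A day after removal of the PE filter, b,pl against CA had 2 cDNAs of the enolase gene eno2 (LOC542316) at 0.75 (SE 0.21) and 0.41 (SE 0.16), a linker histone his1a (LOC541964) cDNA at 0.72 (SE 0.27), HMT-2 (LOC541874) at 0.58 (SE 0.23) and cgs1 at 0.41 (SE 0.18). Of these 5 cDNAs 0 passed (limma adjusted p = 1), and each turned negative with the sign of b,pl PE removed replicate 1 turned, a change that took the median residual variance from 0.168 to 0.161. The array of this pair with conflicting dye labels is replicate 2, and turning it instead gave 0.167. Values with replicate 2 turned were not computed, so only 1 of the 2 possible reversals is shown. HSP70 and the heat shock list written beforehand had medians of −0.08, and mitochondrial membrane proteins 0.13, which was −0.03 without centring, where all cDNAs had −0.16. Without b,pl PE removed replicate 1 the 3 lists stood at 0.0011, −0.0145 and 0.034, and without replicate 2 the first pair at −0.17. With replicate 1 turned, and likewise read as group over other channel, they stood at 0.0023, 0.0023 and 0.058. With scaled arrays the heat shock list stood at −0.12 and mitochondrial membrane proteins at 0.19. The list calls were lost (adjusted p = 0.984 to 0.986 with an estimated correlation). Over all cDNAs 0 passed in limma and 55 had an unadjusted p under 0.05, against 270 by chance. The count was 3 without b,pl PE removed replicate 2.

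Against plants still under PE, b,pl after removal had 57 of 58 elongation factor 1-alpha cDNAs positive (median 0.34) and ribosomal proteins at 0.25. The b,pl PE group enters here and in b,pl under PE against CA with opposite signs, so the values of both comparisons partly mirror each other. Elongation factor 1-alpha was not called in b,pl PE removed minus CA. Without b,pl PE replicate 2 these medians were −0.0085, with 28 of 58 positive, and 0.15, without PE removed replicate 1 they were 0.11 and 0.032, without PE removed replicate 2 0.64 and 0.505, and without b,pl PE replicate 1 the first was 0.735. The directions of b,pl PE replicate 2 and PE removed replicate 1 are both in doubt, since turning either sign lowered the median residual variance from 0.168, to 0.158 and 0.161. Turning their dye swaps instead, b,pl PE replicate 1 and PE removed replicate 2, gave 0.164 and 0.167, and list values for that were not computed. With b,pl PE replicate 2 turned the medians were −0.48, with 57 of 58 elongation factor cDNAs negative, and −0.16. With PE removed replicate 1 turned they were 0.27 and 0.0056, and read as group over other channel −0.62 and −0.38. With scaled arrays elongation factor 1-alpha stood at 0.16. Single cDNAs stood at 1.92 (SE 0.67) for the sucrose synthase sh1 (LOC542365), −1.44 (SE 0.52) for HDT1, 1.09 (SE 0.40) for LOC542657, −1.13 (SE 0.43) for sam2 and 1.62 (SE 0.61) for fdh1. These 5 cDNAs did not pass (limma adjusted p = 0.999) and took the opposite sign with b,pl PE replicate 2 turned, and the list calls were lost (adjusted p = 0.984 with an estimated correlation). Limma passed 0 cDNAs, and 145 had an unadjusted p under 0.05, against 270 by chance. The count was 370 without b,pl PE replicate 1, where all of these 5 but sam2 passed, and 2 without b,pl PE removed replicate 2.

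In B,Pl after removal against PE, 56 of 58 elongation factor 1-alpha cDNAs (median 0.35), 38 of 43 HSP70 cDNAs (0.33) and 13 of 15 ribosomal protein cDNAs (0.44) were positive, while linker histones H1 stood at −0.155 and the heat shock list written beforehand at 0.32. The B,Pl PE group enters B,Pl under PE against CA with the opposite sign, so the HSP70 values of both comparisons are not independent. Without B,Pl PE replicate 3 elongation factor 1-alpha stood at 0.085, HSP70 at 0.54 and the heat shock list at 0.53, and without B,Pl PE replicate 2 the last 2 at 0.17 and 0.165. With the sign of B,Pl PE replicate 3 turned, which took the median residual variance from 0.168 to 0.152, elongation factor 1-alpha stood at −0.15 with 47 of 58 cDNAs negative, ribosomal proteins at 0.093, HSP70 at 0.59 and the heat shock list at 0.57. As group over other channel elongation factor 1-alpha stood at −0.18, linker histones at 0.098 and ribosomal proteins at 0.040. Both cDNAs of the reversibly glycosylated polypeptide LOC542592 were at 1.62 (SE 0.38) and 1.24 (SE 0.30), 1 of hsp70-5 at 1.43 (SE 0.45), LOC541999 at 1.28 (SE 0.38) and LOC541703 at −0.72 (SE 0.21). None of these 5 passed (limma adjusted p = 0.962), nor did the lists (adjusted p = 0.984 with an estimated correlation). In limma 0 cDNAs passed and 240 had an unadjusted p under 0.05, against 270 by chance. The count was 8 and 2 without B,Pl PE removed replicates 1 and 2.

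In the greenhouse, b,pl with UV-B against b,pl without UV-B (1 array) had HSP70 at a median of −0.55, with 39 of 43 cDNAs negative, and 1 cDNA of hsp70-4 at −1.14 (SE 0.30). Ribosomal proteins (−0.48), the heat shock list written beforehand (−0.48) and glycolysis genes (−0.23) were negative. Tubulins (0.53), mitochondrial membrane proteins (0.31) and elongation factor 1-alpha (0.22) were positive. Without b,pl UV-B replicate 1 ribosomal proteins stood at −0.31, tubulins at 0.27 and elongation factor 1-alpha at 0.49, and without replicate 2 the first was at −0.79 and the last at 0.077. With the sign of replicate 2 turned, which raised the median residual variance to 0.205, ribosomal proteins stood at −0.195 and glycolysis genes at −0.072. Elongation factor 1-alpha stood at 0.099 with B,Pl PE replicate 3 turned, at 0.11 with b,pl PE replicate 2 turned, and at 0.039 read as group over other channel, where glycolysis genes stood at −0.15. Named cDNAs stood at 1.74 (SE 0.35) for PP1 (LOC542269), 1.46 (SE 0.33) for LOC542358, 1.18 (SE 0.27) for ANT1 and 1.84 (SE 0.48) for LOC541942. Of these 5 cDNAs 0 passed (limma adjusted p = 0.712), and the list calls were lost (adjusted p = 0.984 to 0.986 with an estimated correlation). Over all cDNAs 0 passed in limma and 325 had an unadjusted p under 0.05. The count was 1 without b,pl UV-B replicate 1 or 2.

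Against b,pl under CA, b,pl at greenhouse UV-B had 53 of 56 cDNAs of the S-adenosylmethionine and inositol list positive (median 0.85), and 34 passed over the list alone. This comparison cannot separate UV-B from other differences between greenhouse plants and plants under the CA filter. The list was not called in greenhouse UV-B minus no UV-B. By dye label sam2 and INO1 were also positive on the greenhouse array without UV-B. Aquaporins stood at 0.48 with the plasma membrane water channel PIP1-1 (LOC542434) at 1.83 (SE 0.36). Other cDNAs stood at 0.94 (SE 0.19) for LOC542358, 1.03 (SE 0.23) for the malate dehydrogenase mdh4 (LOC542598), 0.88 (SE 0.20) for PP1 and 1.13 (SE 0.26) for sam2. These 5 cDNAs did not pass (limma adjusted p from 0.139 to 0.152), and 4 of them turned negative with the sign of b,pl UV-B replicate 2 turned, a change that raised the median residual variance from 0.168 to 0.205. Tubulins were at 0.20, ribosomal proteins at −0.455 and linker histones H1 at −0.30. These were 0.012 and −0.22 for the first and second without b,pl UV-B replicate 1, and 0.33, −0.74 and −0.17 without replicate 2, where aquaporins stood at 0.083. With the sign of replicate 2 turned, and likewise read as group over other channel, the S-adenosylmethionine and inositol list stood at −0.15 with 45 of 56 cDNAs negative, aquaporins at −0.17, linker histones at 0.135 and ribosomal proteins at −0.082. The list calls were lost (adjusted p = 0.984 to 0.986 with an estimated correlation). Limma passed 0 cDNAs, and 701 had an unadjusted p under 0.05; the smallest adjusted p was 0.0515, 2 passed without b,pl UV-B replicate 1, and 10 with the sign of B,Pl PE replicate 3 turned, the PIP1-1 cDNA among them.

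Between genotypes at greenhouse UV-B, all 3 comparisons subtract the same b,pl UV-B group, so they are not independent of each other. That group enters b,pl UV-B against no UV-B with the opposite sign, so values there partly mirror these. B,Pl minus b,pl had 56 of 58 elongation factor 1-alpha cDNAs negative, at a median of −0.92, with cDNAs of elfa2 at −1.70 (SE 0.46) and elfa3 at −1.11 (SE 0.30). Others stood at −1.38 (SE 0.27) for ANT1, −1.84 (SE 0.45) for LOC542185 and 3.61 (SE 0.95) for MCM6 (LOC542206), a subunit of the replicative helicase. None of these 5 passed (limma adjusted p from 0.323 to 0.623). Mitochondrial membrane proteins stood at −0.32, translation factors of the list written beforehand at −0.62 and calcium and phosphatase signalling genes at 0.30, which was 0.19 and 0.62 without b,pl UV-B replicates 1 and 2 and 0.45 with the sign of replicate 2 turned. The list calls were lost (adjusted p = 0.984 with an estimated correlation). In limma 1 unnamed cDNA passed, at spot 6997 with 5.90 (SE 0.65, adjusted p = 0.0326), and 304 had an unadjusted p under 0.05. It was 0 without any 1 of 10 arrays: the 2 b,pl and 2 B,Pl PE removed arrays, B,Pl PE replicates 1 and 2, both b,pl UV-B and both bz2 LE arrays. The count was 3 without b,pl PE replicate 1 or 2, and 2, both positive, with the sign of the latter turned.

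For bz2 minus b,pl at greenhouse UV-B, both cDNAs of the reversibly glycosylated polypeptide LOC542592 stood at 2.46 (SE 0.51) and 1.62 (SE 0.41), 1 of LOC541942 at 2.90 (SE 0.66), 1 of his1a at 1.32 (SE 0.31) and 1 of LOC732721 at 2.41 (SE 0.49). Of these 5 cDNAs 0 passed (limma adjusted p from 0.295 to 0.411). Ribosomal proteins (0.53) and calcium and phosphatase signalling genes (0.44) were positive and tubulins negative (−0.35), calls that were lost (adjusted p = 0.984 with an estimated correlation). In b,pl UV-B against no UV-B, where the b,pl UV-B group has the opposite sign, ribosomal proteins stood at −0.48 and tubulins at 0.53. Without b,pl UV-B replicate 1 the 3 medians were 0.20, 0.25 and −0.16, and without replicate 2 that of ribosomal proteins was 0.81, against 0.082 with its sign turned and 0.30 read as group over other channel. In limma 2 unnamed cDNAs passed, at spot 3049 with 4.76 (SE 0.32, adjusted p = 0.000109) and at spot 10738 with 5.42 (SE 0.69, adjusted p = 0.0286), and 262 had an unadjusted p under 0.05, against 270 by chance. The count was 35 with scaled arrays, 23 of them positive, among which were the LOC732721, LOC541942 and his1a cDNAs and 1 of LOC542592, and 1 without any 1 of the b,pl or B,Pl PE removed, b,pl PE, B,Pl PE, b,pl UV-B or bz2 LE arrays or B,Pl CA replicate 1. Read as group over other channel 1 cDNA passed, and it was negative, whereas both above are positive.

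For mutator minus b,pl at greenhouse UV-B, 95 of 117 tubulin cDNAs were negative (median −0.62), with tua4 cDNAs at −2.20 (SE 0.36) and −1.48 (SE 0.42) and 25 of 30 cDNAs of the alpha-tubulin TUA1 (LOC100037751) negative. LOC542358 stood at −1.42 (SE 0.33) and the glutathione S-transferase gst41 (LOC541849) at 1.20 (SE 0.33). Of the 5 cDNAs selected here, 1 of TUA1 included, 0 passed (limma adjusted p from 0.488 to 0.774). HSP70 (0.45), ribosomal proteins (0.42), the heat shock list written beforehand (0.41), calcium and phosphatase signalling (0.39) and glycolysis genes (0.21) were positive, and elongation factor 1-alpha was negative (−0.43). The b,pl UV-B group has the opposite sign in b,pl UV-B against no UV-B, where HSP70 stood at −0.55, ribosomal proteins at −0.48 and tubulins at 0.53. Without b,pl UV-B replicates 1 and 2 ribosomal proteins stood at 0.22 and 0.72, signalling at 0.25 and 0.61, glycolysis genes at 0.13 and 0.38 and elongation factor 1-alpha at −0.65 and −0.23, and without replicate 1 tubulins at −0.37. With the sign of replicate 2 turned ribosomal proteins stood at 0.12 and glycolysis genes at 0.115, and as group over other channel ribosomal proteins at 0.27 and elongation factor 1-alpha at −0.205. The list calls were lost (adjusted p = 0.984 with an estimated correlation). In limma 0 cDNAs passed and 317 had an unadjusted p under 0.05. The count was 1 without b,pl UV-B replicate 1.

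Under the CA filter, B,Pl minus b,pl had 40 of 43 HSP70 cDNAs (median 0.32) and 86 of 117 tubulin cDNAs (0.29) positive, with the heat shock list written beforehand at 0.31. The B,Pl CA group enters B,Pl under PE against CA with the opposite sign, so the negative HSP70 and tubulin medians there are not independent of these. The tubulin median was 0.12 without B,Pl PE replicate 1 and 0.45 without B,Pl CA replicate 2. As group over other channel HSP70 and the heat shock list stood at 0.084 and 0.080, and the 5 cDNAs named next took the opposite sign. Single cDNAs stood at 0.78 (SE 0.18) for tua4, 0.75 (SE 0.21) for TUA1, −0.57 (SE 0.13) for stomatin1, 1.28 (SE 0.33) for sdg110 (LOC542662) and 1.49 (SE 0.42) for the linker histone hon101 (LOC541973). These 5 cDNAs did not pass (limma adjusted p = 0.463), and the list calls were lost (adjusted p = 0.984 with an estimated correlation). Over all cDNAs 0 passed in limma and 569 had an unadjusted p under 0.05.

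For bz2 minus b,pl under CA, with 1 array, 42 of 43 HSP70 cDNAs were positive at a median of 0.25, which was −0.18 without centring, where all cDNAs had −0.44, as the heat shock list written beforehand went from 0.23 to −0.20. Aquaporins (−0.24), linker histones H1 (−0.19), tubulins (−0.15) and the carbon fixation and sugar list written beforehand (−0.22) were negative. The dye labels of the bz2 CA array conflict, so every sign in this comparison rests on its title. With that array turned the median residual variance stayed at 0.168, which cannot settle the direction of a group with 1 array. Aquaporins stood at −0.15 with the sign of b,pl PE replicate 2 turned, and linker histones at −0.125 read as group over other channel. Named cDNAs stood at −1.72 (SE 0.43) for PDHE1-B (LOC541705), a pyruvate dehydrogenase subunit, 0.94 (SE 0.33) for LOC542592, 1.03 (SE 0.41) for LOC541999, −0.55 (SE 0.23) for AGP2 (LOC542737) and −0.52 (SE 0.22) for the aquaporin PIP2-1 (LOC541888). None of these 5 passed (limma adjusted p = 1), nor did the lists (adjusted p = 0.984 with an estimated correlation). Limma passed 0 cDNAs, and 28 had an unadjusted p under 0.05, against 270 by chance. With scaled arrays 1 passed, the PDHE1-B cDNA at −2.37.

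For mutator minus b,pl under CA, with 1 array, 57 of 58 elongation factor 1-alpha cDNAs were negative (median −0.56), 1 of them, of EF1A (LOC542581), at −2.71 (SE 0.46). The S-adenosylmethionine and inositol list (−0.33), mitochondrial membrane proteins (−0.27) and the translation factor list written beforehand (−0.45) were negative too. This array also has conflicting dye labels, so every sign here rests on its title. Turning it left the median residual variance at 0.168, which cannot settle the direction of a group with 1 array. As group over other channel elongation factor 1-alpha stood at −0.33, the S-adenosylmethionine and inositol list at −0.85 and the translation factor list at −0.28. Single cDNAs stood at −1.18 (SE 0.22) for ANT1, −1.32 (SE 0.29) for the alcohol dehydrogenase adh1 (LOC542363), −1.71 (SE 0.43) for PDHE1-B and −1.07 (SE 0.27) for LOC542358. Of these 5 cDNAs 0 passed (limma adjusted p from 0.533 to 0.947), and the list calls were lost (adjusted p = 0.984 with an estimated correlation). In limma 0 cDNAs passed and 252 had an unadjusted p under 0.05, against 269 by chance.

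Over the 437 list tests, which include 18 lists written after the annotation and the correlations between arrays were seen, 81 passed with the preset correlation, 0 with an estimated correlation (7 at unadjusted p under 0.05), and 0 when the cDNAs of a gene were averaged first, where 11 of the 81 had too few genes to test. Some lists hold many cDNAs of few genes, such as HSP70 with 43 cDNAs of 2 genes, and estimated correlations between list members ran from −0.06 to 0.696. Of the lists written beforehand, heat shock proteins and chaperones passed in 12 of 19 comparisons, 5 positive and 7 negative, with at most 3 cDNAs passing adjusted over the list alone and 1 over all cDNAs. These calls add little to those of HSP70, which passed in 11, since both lists appear to share most of their cDNAs. Translation factors passed in 4, with at most 1 and 0 cDNAs, and carbon fixation and sugar metabolism in 1, with 0 and 0. DNA repair and replication and histones and chromatin passed in 0, with smallest camera adjusted p of 0.0981 and 0.103 and at most 1 and 0 cDNAs adjusted over the list alone. Of the later lists, core histones and chromatin proteins (0.0823), endoplasmic reticulum chaperones (0.114), glutathione S-transferases and antioxidant enzymes (0.0792), oxylipin synthesis (0.265), cell cycle and DNA replication (0.202) and developmental transcription factors (0.103) passed in 0 comparisons, with the smallest camera adjusted p of each given in parentheses.

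**Figure D2:**
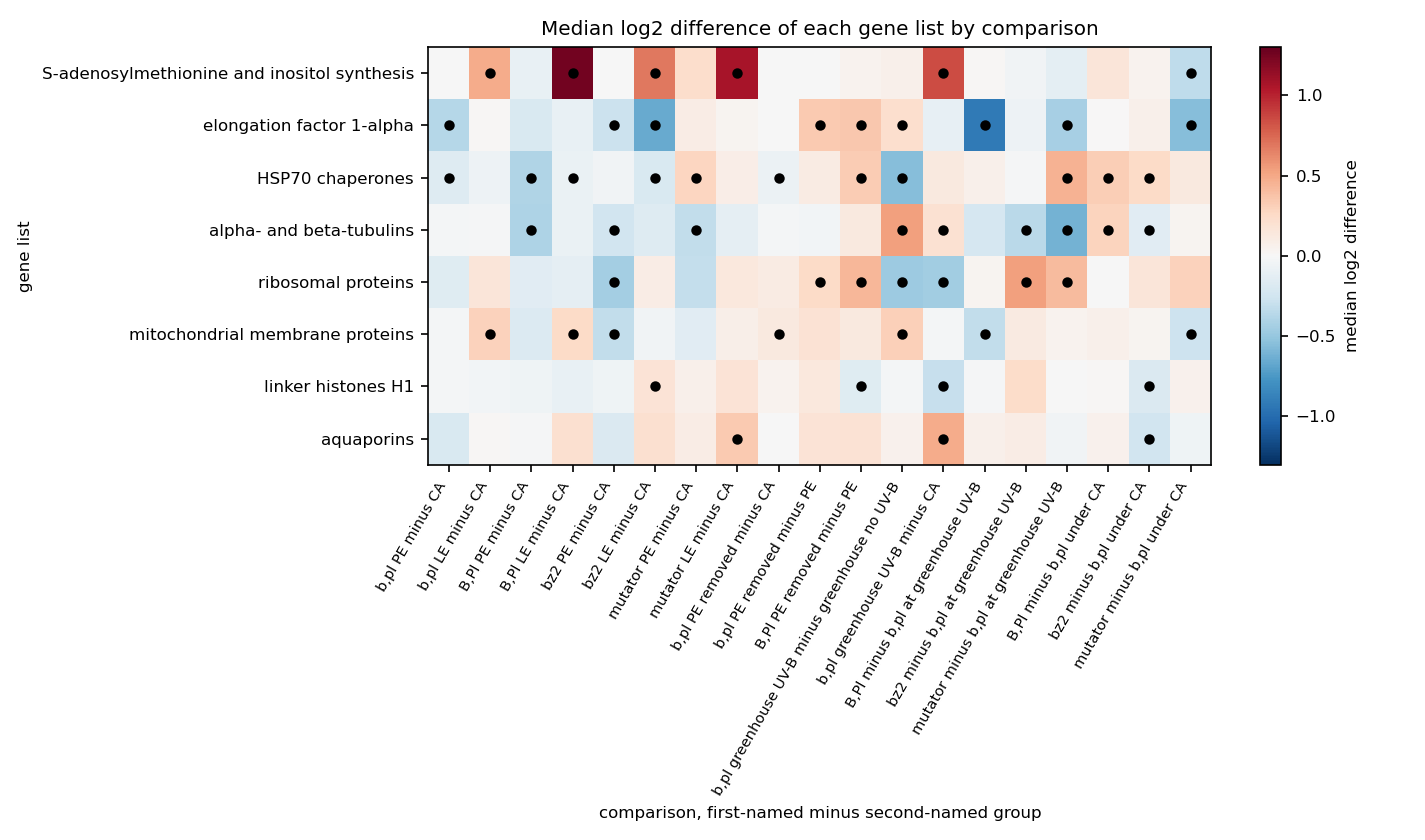
Median log2 difference (colour scale) of 8 gene lists (vertical axis) in the 19 comparisons, first-named minus second-named group (horizontal axis), with a dot where the list passed at the preset correlation. The S-adenosylmethionine and inositol list has its largest medians, 1.25 and 1.07, in B,Pl and mutator under LE, and 0 of the dots hold with an estimated correlation.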

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

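All tests of explanations here were chosen after the correlations they weigh had been seen, while the test of genotype differences was chosen before.

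The response to LE differed between genotypes for 13 cDNAs in the F test specified beforehand, and 0 of them had a gene name. Of these, 9 also passed in B,Pl under LE, 5 in bz2, 2 in mutator and 0 in b,pl. The cDNA with the smallest adjusted p, 0.000886, began at spot 403 and stood at −3.70 in bz2, −1.33 in mutator, 0.21 in b,pl and 1.99 in B,Pl. For B,Pl and mutator 1 array stands behind each value. The count ran from 2 to 46 when 1 array was left out.

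LE arrays of different genotypes correlated over cDNAs: the 6 pairs of arrays with the LE sample in Cy5 had a median Spearman correlation of 0.37, from 0.28 to 0.50. A dye effect common to the arrays would give Cy3 and Cy5 LE arrays the same sign, but all 6 such pairs lay below 0, with a median of −0.19, which argues against dye as the whole cause; the smaller size leaves room for a share of it. The many named cDNAs of a few genes are not the whole cause either, since cDNAs without a name gave 0.37. Unnamed cDNAs may include further copies of such genes or cross-hybridise with them, so repeated genes in general are not excluded. A response to LE shared by genotypes may account for the rest and stays a hypothesis, found and tested on the same arrays. Other differences between filters were not tested.

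PE arrays of B,Pl, bz2 and mutator with the PE sample in Cy5 correlated between genotypes, at 0.34 to 0.66 over 5 pairs, while the 3 pairs with b,pl PE replicate 1 stood at −0.06, 0.08 and 0.1, and all 8 had a median of 0.38. Pairs whose other channels held the same group were left out, among them b,pl PE replicate 1 with B,Pl PE replicate 2. The low values with b,pl go against a dye effect on every PE array, but rest on 1 array and the 3 pairs kept. The same rule kept 5 pairs of opposite dye, with a median of −0.04. It left out b,pl PE replicate 2 with B,Pl PE replicate 2 and b,pl PE replicate 1 with B,Pl PE replicate 3. Of the pairs kept, the 2 with B,Pl PE replicate 3 lay above 0 and the 3 with b,pl PE replicate 2 below 0. A dye effect and a response to PE cannot be told apart with so few pairs. A wrong dye label on B,Pl PE replicate 3 may play a part: with its sign turned the median residual variance was 0.152, against 0.168 as labelled. Its dye swap, B,Pl PE replicate 2, has conflicting dye labels, and with that array turned instead the variance was 0.166. Turning 2 arrays lowered it by over 5 percent, and both were the PE arrays labelled Cy3, so a label error on 1 array and a difference between dyes under PE stay open alike.

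LE arrays of bz2, mutator and B,Pl correlated with greenhouse arrays, with values turned by dye label to group minus other channel. Both b,pl LE arrays were left out, since their other channel held b,pl CA as on the greenhouse arrays. Of the pairs with the same dye, 15 of 16 lay above 0, with a median of 0.22. In pairs of opposite dye the median was 0.10, with 6 of 8 above 0. A dye effect would put those below 0 and a shared response above 0, and with pairs on both sides the explanations cannot be told apart. The PE arrays without b,pl CA in the other channel were B,Pl PE replicate 1, bz2 PE and mutator PE. With greenhouse arrays of the same dye they had a median of −0.12, with 14 of 15 pairs below 0. With the greenhouse array of opposite dye the median was −0.12, with 3 of 3 pairs below 0. The same-dye values go against a dye effect common to these PE and greenhouse arrays but leave open one in LE and greenhouse arrays alone. The pairs in this paragraph reuse a few arrays, and all greenhouse arrays carry b,pl CA RNA in the other channel. These counts are therefore not of independent observations. PE arrays with b,pl CA in the other channel were left out.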

How the results depend on the processing

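Readings as group over other channel, turned signs, omission of the 3 arrays with the most missing values, gene averages and the averaged comparisons were chosen after the data were seen. Robust shrinkage and no filter on missing values moved no count by over 1.5 times; the filter removed no cDNA, so that alternative tests nothing. No paired analysis was possible because the labels give no replicate numbers. Channel intensities were not analysed here, so limits from signal over background are not known. Where counts or signs moved, the cause was not tested, except that gene averages test fewer genes.

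Without centring, 1 cDNA passed in bz2 under PE, 6 in bz2 under LE, 2 in B,Pl minus b,pl at UV-B, 2 in the LE average and 1 in the LE F test. Without a dye term, 1 passed in bz2 under PE, 1 in b,pl UV-B minus CA and 3 in B,Pl minus b,pl at UV-B. With arrays scaled to 1 spread, counts were 48 in B,Pl under LE, 2 in bz2 under PE, 12 in bz2 under LE, 5 in b,pl PE removed minus CA, 35 in bz2 minus b,pl at UV-B, 1 in bz2 minus b,pl under CA, 120 in the LE average and 27 in the LE F test. Over complete cDNAs, 1 passed in b,pl UV-B minus CA and 0 in B,Pl minus b,pl at UV-B (limma; 304 at unadjusted p under 0.05 over all cDNAs). Changes over 2-fold with the same sign on both side-by-side arrays numbered 322 in b,pl under PE, 160 in b,pl under LE, 262 in bz2 under LE, 62 in b,pl PE removed minus CA, 200 in b,pl UV-B minus CA and 190 in B,Pl minus b,pl under CA. The share of cDNAs with the same sign on both arrays was 45.8%, 58.1%, 72.7%, 44.2%, 64.1% and 50%, against 50% by chance.

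With the sign of B,Pl PE replicate 3 turned, counts were 1 in bz2 under PE, 53 in bz2 under LE, 10 in b,pl UV-B minus CA, 3 in B,Pl minus b,pl at UV-B and 107 in the LE average. With b,pl PE removed replicate 1 turned they were 2 in b,pl UV-B minus CA, 1 in mutator minus b,pl under CA and 115 in the LE average. With b,pl PE replicate 2 turned, which lowered the median residual variance to 0.158, the count was 2 in B,Pl minus b,pl at UV-B. With b,pl UV-B replicate 2 turned, which raised the median residual variance to 0.205, they were 1 in UV-B minus no UV-B, 1 in UV-B minus CA and 13 in the LE average. Without the 3 arrays with the most missing values they were 16 in bz2 under LE, 2 and 4 in B,Pl and bz2 minus b,pl at UV-B and 0 in the LE average. Averaged by gene, 2 genes passed in b,pl under LE, 0 in B,Pl, bz2 and mutator under LE (limma; 10, 29 and 6 at unadjusted p under 0.05), 6 in b,pl UV-B minus CA, 0 (13 unadjusted) and 1 in B,Pl and bz2 minus b,pl at UV-B, and 4 in the LE average. Of the 81 list calls 0 passed with an estimated correlation or by gene average, 73 passed without a dye term and 68 without centring.

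Read as group over other channel, counts were 1 in bz2 under PE, 14 in bz2 under LE, 0 and 1 (negative) in B,Pl and bz2 minus b,pl at UV-B and 3 in the LE average, and 33 of 90 named values took the opposite sign. In b,pl under PE these were CaM1 0.58, HDT1 −0.91, LOC542657 0.80 and fdh1 1.297, values that b,pl PE replicate 2 turned gave too. In b,pl under LE they were LOC542592 −0.51 and −0.051, tua5 0.43, cgs1 −0.28 and PEAMT 0.98. In bz2 under LE they were hsp70-4 −0.15, eno1 −0.18, elfa2 0.15 and elfa3 0.18. In b,pl PE removed minus PE they were sh1 −1.87, HDT1 0.70, LOC542657 −0.77 and fdh1 −1.16 (with b,pl PE replicate 2 turned sh1 −0.69, HDT1 0.895, LOC542657 −0.83, sam2 0.18 and fdh1 −1.303), and in B,Pl LOC541999 −0.19 and hsp70-5 −0.80. In B,Pl minus b,pl under CA they were tua4 −0.20, stomatin1 0.069, sdg110 −0.40, hon101 −0.69 and TUA1 −0.16. In b,pl PE removed minus CA, eno2 took −0.34 and −0.097, his1a −0.69, HMT-2 −0.33 and cgs1 −0.12, both under this reading and with b,pl PE removed replicate 1 turned. In b,pl UV-B minus CA, PIP1-1 took −0.47, mdh4 −0.0014, PP1 −5.6e-05 and sam2 −0.20, both under this reading and with b,pl UV-B replicate 2 turned.

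Leaving out 1 array in turn, counts ran from 0 to 645 in b,pl, 0 to 0 in B,Pl, 0 to 1 in bz2 and 0 to 0 in mutator under PE, and from 0 to 103, 7 to 16, 11 to 34 and 3 to 6 in the same genotypes under LE. They ran from 0 to 3 in b,pl PE removed minus CA, 0 to 370 and 0 to 8 in b,pl and B,Pl PE removed minus PE, 0 to 1 in UV-B minus no UV-B and 0 to 2 in UV-B minus CA. At UV-B they ran from 0 to 3, 1 to 3 and 0 to 1 in B,Pl, bz2 and mutator minus b,pl, and under CA from 0 to 0 in each. The LE and PE averages ran from 0 to 97 and 0 to 211, and the PE and LE F tests from 0 to 204 and 2 to 46. The arrays behind the extremes were b,pl PE replicate 1 for 645, 370, 211 and 204, b,pl LE replicate 1 for 103 and 46, and b,pl LE replicate 2 for 0 in the LE average.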

Other observations

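The tests by array and the averages over the cDNAs of a gene were chosen after the results were seen.

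Read by dye label as group minus other channel, INO1 and sam2 lay on 1 side on every LE and every greenhouse array, and read as group over other channel they were positive on 4 of 6 LE and 5 of 6 greenhouse arrays. By dye label each array gave 1 value for INO1, taken over its 19 cDNAs. The array values averaged 0.99 ± 0.33 (SD between arrays) on LE arrays, positive on 6 of 6. On greenhouse arrays they averaged 1.27 ± 0.345, positive on 6 of 6, including the array without UV-B. For sam2, with 32 cDNAs, the averages were 0.62 ± 0.31 and 0.48 ± 0.27, again positive on 6 of 6 arrays in each set. On the 5 PE arrays against CA plants of the same genotype both genes were positive on 2 and negative on 3; on B,Pl PE replicates 2 and 3, against b,pl under CA, INO1 stood at −0.70 and 0.63 and sam2 at −0.565 and 0.55. The exact sign-flip p was 0.0312 for each of the 4 LE and greenhouse averages, the smallest that 6 arrays can give. This test takes the 6 arrays as independent, which they are not: all greenhouse arrays carry b,pl CA RNA in the other channel, 3 of them against another genotype, and the dye swaps of b,pl LE, bz2 LE and b,pl UV-B count as separate arrays. Over 57 tests of 19 genes in 3 sets the adjusted sign-flip p was 0.111 and 0 passed, and 16 of the 57 had the smallest possible p. With that floor, a test could pass the adjustment only if most of the 57 sat at it. The failure to pass is therefore no evidence against a difference.

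When the cDNAs of a gene were averaged before the limma fit, 213 genes or fewer were tested in place of all cDNAs. Of the genes below, cgs1, LOC542358, PIP1-1, mdh4, AGP2 and GRF12 have 1 cDNA each, so nothing was averaged for them. In limma over all cDNAs, cgs1 in b,pl under LE had an adjusted p of 0.55. In b,pl at greenhouse UV-B against CA, LOC542358, PIP1-1 and mdh4 lay between 0.139 and 0.152. In b,pl under LE, the reversibly glycosylated polypeptide LOC542592 stood at 1.44 (limma adjusted p = 0.0075) and cgs1 at 0.85 (limma adjusted p = 0.0398). Read as group over other channel, the LOC542592 cDNAs stood at −0.51 and −0.051 and cgs1 at −0.28. For the average of genotypes under LE, cgs1 (0.68, limma adjusted p = 0.0127), sam2 (0.76) and eno1 (0.56, both limma adjusted p = 0.0272) and LOC542592 (0.66, limma adjusted p = 0.0293) passed, and INO1 at 1.15 did not (limma adjusted p = 0.059). In b,pl at greenhouse UV-B against CA, 6 genes passed: LOC542358 (0.94) and PIP1-1 (1.83), both at limma adjusted p = 0.0287, mdh4 (1.03) and AGP2 (0.69), both at 0.033, and GRF12 (0.72) and LOC542657 (−0.67), both at 0.044. This comparison cannot separate UV-B from other differences between greenhouse plants and plants under the CA filter. With b,pl UV-B replicate 2 turned, which raised the median residual variance to 0.205, the PIP1-1 and mdh4 cDNAs stood at −0.47 and −0.0014. For bz2 minus b,pl at greenhouse UV-B, LOC542592 passed at 2.04 (limma adjusted p = 0.049).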
